A study of Sphingomonas sp. LH128 with 9 samples.

How the data were processed

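The series holds 9 one-colour arrays of Sphingomonas sp. LH128, a soil bacterium that degrades phenanthrene, a polycyclic aromatic hydrocarbon. Per the labels' protocols, cells were grown in minimal medium with 2 g of glucose per litre and added as 160 µl of suspension to 2 g of soil that held phenanthrene at 500 mg per litre. The soil stood at 20 °C, and replicate tubes were taken after 4 h and after 10 d. The initial inoculum, the soil at 4 h and the soil at 10 d have 3 arrays each, grouped by their titles. The source labels of 10 d replicates 2 and 3 name other days than their titles, descriptions and time labels, which all give 10 d, and the titles were followed. Per the labels' protocols, soil RNA and inoculum RNA were extracted with different kits, so the kit and the step from culture to soil cannot be separated by design. The soil replicates were separate tubes per the labels. Where nothing says that the inoculum replicates came from separate cultures, p-values measure only the spread between these samples, which may be technical.

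Per the labels' protocols, 4 µg of RNA per sample was labelled with Cy3. Per the file headers, arrays were scanned and extracted with Agilent Feature Extraction 10.7.1.1, which gave for each spot an intensity after background subtraction and flags for signal well above background, saturation and outliers. The authors also deposited a table of log2 values, 1 row per probe identifier. Its array medians were 0.01 on each inoculum array, -0.01 on each 4 h array and 0.02, 0.01 and 0.02 on the 10 d arrays. Its direction was that of the scanner values, and its exact centring and normalization are not given in the sources used here.

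The array carried 12863 non-control spots for 7033 reading frames. Of these frames, 1402 had 1 spot, 5611 had 2 and 20 had 11 or 12. The 2 spots of a frame differed by a median of 1.11 (log2), and that difference correlated between inoculum and 4 h arrays with r of at least 0.918 across 3371 frames. Such spots were therefore read as different probes. Identifiers are start and end coordinates on an unnamed assembly, and its build is not given in the sources used here. A start above the end was read as the reverse strand. Every length was a multiple of 3, so lengths are coding lengths. The files pair no identifier with a gene name. For that reason the 32 gene lists fixed before the data were examined could not be applied, and at most 2 identifiers per direction are printed, those with the greatest change at 4 h among called frames measured in both groups whose arrays did not overlap.

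The main values were log2 processed signal minus each array's 75th percentile over non-control spots. Spots flagged as outliers were left out, saturated spots were not, and the spots of a frame were averaged. A frame counts as measured in a group when at least 1 spot was well above background on all 3 arrays. Its mean over spots can still lie below the array limits, as in 17 of 514 measured calls at 4 h and 131 of 1142 at 10 d against the inoculum. The 6353 frames measured in at least 1 group were tested. A group mean over all 9 arrays was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 6 residual degrees of freedom, two-sided). Benjamini-Hochberg adjustment ran over all frames of a comparison, and a frame was called at an adjusted p under 0.05. Where a frame was well above background on no array of the dimmer group, the change is given as "at least N-fold". The same form is used for a named frame that was measured in the dimmer group with a mean over spots below an array's limit. That bound sets the bright group's mean against the mean, over the dim group's arrays, of the higher of 2 values, the array's lowest signal well above background and the frame's own.

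After the identifiers proved to be coordinates, regions and runs were added. Frames were put into bins of 20 kb by their midpoints, bins with at least 5 tested frames were tested with camera at a preset correlation of 0.01, and neighbouring called bins of one direction were joined. The 5 regions per direction with the greatest median change are named. The comparison at 4 h used all tested frames and those with 10 d used frames measured in both groups. A run is a series of neighbouring frames on one strand with gaps of at most 50 nt and at least 3 tested frames. Run counts were set against 1000 shuffles of the calls over the frames. The shuffles did not keep the signal level of the frames.

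The fit was tested on simulated data of 6349 frames in 10 simulations, with 100 frames changed 2-fold and 100 changed 4-fold and the spread of each group kept. With each frame's own spread, 40.0% of 2-fold and 82.5% of 4-fold changes were recovered for 4 h against the inoculum, and 2.34% of calls were false. For 10 d against the inoculum, 45.3% and 83.1% were recovered and 39.1% of calls were false. With moderated spreads the false shares were 0.297% and 22.5%. Fitting only the 6 arrays compared gave false shares of 15.2% and 2.20% at 10 d under the same spreads in turn, and 8.46% and 6.64% at 4 h. A false share depends on how many frames change, so these shares compare fits and do not carry over to the real calls. No simulated value was held at a lowest signal, as many 10 d spots were. The shares recovered at 10 d therefore do not carry over either, and may be too high for falls. The 9-array fit was fixed in advance and was kept as the main fit. The fit averages the spread of the noisy 10 d arrays with that of the others, so it is strict at 4 h and too lenient at 10 d, and the 6-array counts stand beside its counts in the results.

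All inoculum and 4 h arrays lay on 1 slide and all 10 d arrays on another, so slide and the 10 d group cannot be told apart, and a slide block could not be fitted. Whether replicate numbers pair arrays is not settled. Deviations of same-numbered inoculum and 4 h arrays correlated with r = 0.321, 0.134 and 0.099, while 4 of the 6 other pairs were negative, and inoculum replicate 2 correlated as well with 4 h replicate 3 (0.135). The pairs with 10 d arrays had r between -0.047 and 0.062. Pairing was to be accepted only with every same-numbered pair over 0.1, so the block was kept as an alternative. Settings chosen before the data were examined were quantile and median scaling, normexp with an offset of 50 followed by the 75th percentile or by quantile scaling, the authors' values, no filter, frames measured on all 9 arrays, single probes, the 6 arrays compared, blocks for replicate number and array row, stricter thresholds, trend and robust settings, array weights and leaving out each array. The normexp settings were planned on the mean spot signal, which is not given in the sources used here, and used the median spot signal in its place. Settings chosen after seeing the data were a percentile over spots detected on all 9 arrays, a common floor, frames measured in both groups, bins of 50 kb, estimated correlations and fry. The design fixed counts of frames called at both soil times over all tested frames. Limiting these counts, and their settings, to frames measured on all 9 arrays was also chosen after seeing the data, and the counts over all frames stand beside them for the 9-array fit only. The number of arrays limits the precision of each value. Figures were drawn with matplotlib.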

Results

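The data were 9 arrays, 3 each for the glucose-grown inoculum of Sphingomonas sp. LH128, for the same cells after 4 h in phenanthrene-contaminated soil and for cells after 10 d in that soil. The design asks how transcript levels in soil differ from those of the initial inoculum. Signal differed strongly between groups. The share of spots well above background lay between 78.7% and 80.9% in the inoculum (SD 1.15, n = 3) and was 83.4% ± 0.896 (SD, n = 3) at 4 h and 27.3% ± 9.51 (SD, n = 3) at 10 d. Correspondingly, 6107, 6273 and 1923 of 7033 reading frames were measured on all 3 arrays of these groups. The median SD of a tested frame was 0.14 in the inoculum, 0.14 at 4 h and 0.58 at 10 d (log2). On 10 d replicates 1 and 3, 6258 and 6497 of 12863 spots sat at the lowest value of the array. Replicates correlated across frames with r of at least 0.981 in the inoculum and at 4 h, and with r from 0.856 to 0.920 at 10 d. Frames are named by start and end on the array's unnamed assembly, since the files carry no gene names.

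**Figure D1:**
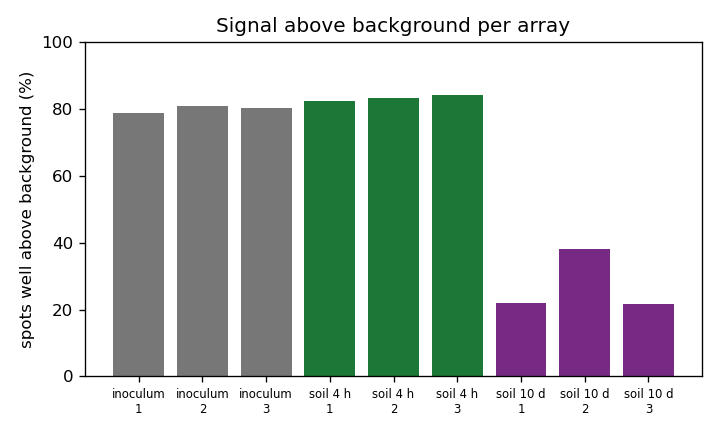
Share of non-control spots well above background (%, vertical axis) on each array, 1 bar per array, coloured by group. The 3 arrays at 10 d lie between 21.8% and 38.3%, and the inoculum and 4 h arrays between 78.7% and 84.3%.

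After 4 h in soil, neighbouring frames between 600128 and 679949 rose together. There, 47 of 79 tested frames were higher than in the inoculum and 0 were lower, with a median change of 1.89 (log2) and rises of up to 142-fold among frames whose mean lay above the array limits in both groups. Another block from 160386 to 179624 had 11 of 18 frames higher and 0 lower, with a median of 1.42. Frame 160386_161594, at its edge, showed the largest rise of all measured frames, 167-fold (log2 change 7.38 ± 0.40 SE, n = 3 per group, limma adjusted p = 2.47e-06). Frame 655149_655253, a reading frame of 105 nt, rose by at least 112-fold (n = 3 per group, limma adjusted p = 3.89e-07), with an inoculum mean below the lowest signal well above background. The largest fall was that of frame 4658569_4658787, by 31.0-fold (log2 change -4.95 ± 0.51 SE, limma adjusted p = 0.000213), followed by frame 2457186_2457500 (log2 change -3.70 ± 0.46 SE, limma adjusted p = 0.000717). Each of these falls rests on 1 spot, with no other probe of the frame to set beside it.

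Rises ran along whole series of frames on one strand. All tested frames rose in 9 of 415 such runs, where shuffled calls gave a mean of 0.026 and at most 1, and 0 runs fell as a whole. The run from 655149 to 659144 on the forward strand (6 frames) had a median change of 5.33. The adjoining run from 659312 to 668655 (11 frames, forward) had a median of 3.86, and the run from 635687 to 643473 (8 frames, reverse) one of 3.07. Outside this stretch, 3 frames from 2410047 to 2412746 rose by a median of 4.51 and 3 frames from 1139188 to 1141276 by a median of 3.81. Runs from 6310237 to 6313255 and from 4732856 to 4734342 rose by medians of 2.03 and 1.93.

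**Figure D2:**
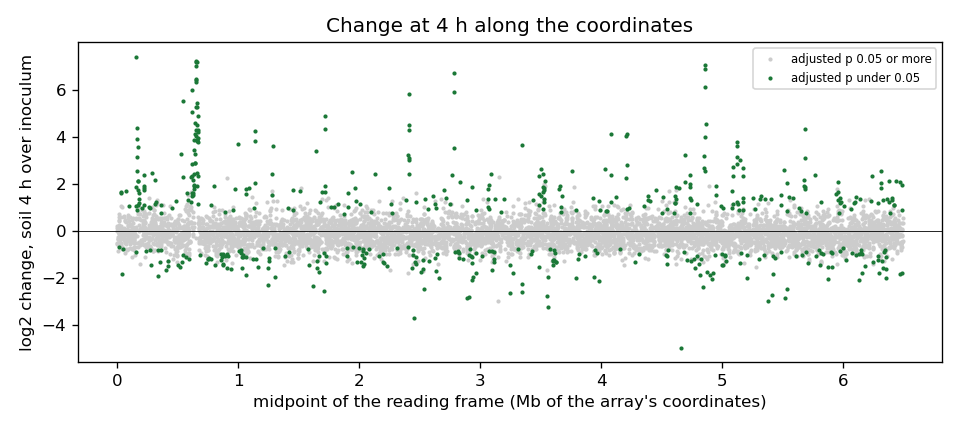
Log2 change at 4 h over the inoculum (vertical axis) against the midpoint of each tested reading frame (Mb of the array's coordinates), 1 point per frame, green where the adjusted p was under 0.05. Between 600128 and 679949, 47 of 79 tested frames are green. The highest green point among frames measured in both groups is frame 160386_161594 (7.38), in another block.

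Further blocks were also called higher as regions. Those from 5120329 to 5139743, from 4199748 to 4220428 and from 2400416 to 2419780 had medians of 0.32, 0.20 and 0.032. They are not among the 5 named ones, of which 3 follow. From 3520085 to 3540138, 8 of 25 frames were higher (median 0.74), from 4600174 to 4619996, 6 of 20 (median 0.45), and from 220009 to 240248, 5 of 27 (median 0.34). The last region changed sign with normexp background correction (-0.023) and among frames measured on all 9 arrays (-0.080). The regions called lower had few called frames, 3 of 25 from 3100013 to 3119653, 4 of 20 from 2439991 to 2460314 and 2 of 29 from 740831 to 760474. In that order they were called in 11, 5 and 13 of 22 other settings, and the region from 220009 to 240248 in 8. In all, camera called 14 of 325 bins, 11 higher and 3 lower. None was called with an estimated correlation, where the smallest adjusted p was 0.052 and 8 bins had an unadjusted p under 0.05, while fry, which tests each bin against no change and not against the other frames, called 17.

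The 20 frames printed 11 or 12 times on the array form a set given by its layout. At 4 h, 10 of them were higher and 0 lower (11 higher adjusted over the list alone), with camera p = 4.73e-16, and p = 0.00103 with an estimated correlation. Of these 20 frames, 8 lie between 652333 and 661105, of which 7 were higher, and their median change was 5.87. The other frames of the set had a median change of 0.43. At 10 d, 14 of the set were measured, of which 9 were higher than in the inoculum and 1 lower, with a median of 1.18 (camera p over the whole set 0.000398, and 0.042 with an estimated correlation), and with normexp the set was not called (p = 0.259). Against 4 h, 3 of the measured frames were higher at 10 d and 7 lower, with a median of -0.98 (camera p over the whole set 0.000627, and 0.047 with an estimated correlation). These camera tests at 10 d also took in the frames of the set not measured there, so they are not tests of the measured medians.

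Over all frames, limma called 314 higher and 242 lower of 6353 at 4 h, and 283 and 231 of these were measured in both groups. Of the rest, 20 were higher and 5 lower only as bounds, of up to at least 71.6-fold. The number depended on the spread shared with the 10 d arrays. Fitting only the 6 arrays compared called 1048 higher and 1741 lower, which included all 556 calls above, and leaving out 10 d replicate 2 gave 786 and 1268. Without a single inoculum or 4 h array the total fell to between 276 and 317. The balance of directions depended on scaling, since 56.5% of calls were higher here, 63.8% with median scaling, 47.1% with quantile scaling, 30.2% with normexp and 22.8% with the percentile taken over spots detected on all 9 arrays. That last scaling moved the median of all frames by -0.29. Relative to the median of all frames, the change from 600128 to 679949 was 2.02 in the main values, 1.78 with quantile scaling, 1.21 with normexp, 0.85 with normexp and quantile scaling and 0.27 with a common floor. In the same order, that from 160386 to 179624 was 1.54, 1.35, 1.52, 1.03 and 0.79, so which of the 2 blocks rose more depends on the scaling. The common floor lifted all dimmer signals to the highest array limit, so it cut rises from a dim inoculum by construction.

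After 10 d in soil, some falls ran along short runs. A run of 3 frames from 2442947 to 2445044 was lower than in the inoculum, with a median log2 change of -3.58. Runs from 5674538 to 5675742 and from 5736995 to 5741303 had medians of -2.27 and -1.94, and 8 tested frames from 746710 to 750499 had one of -1.14. All tested frames fell in 4 of 46 runs, where shuffled calls gave a mean of 0.093 and at most 2. The shuffles did not keep signal level, and changes at 10 d went with the level in the inoculum (r = -0.651). Changes of neighbours within runs correlated with r = 0.602, and with 0.412 after that trend was removed. Frames of like level that fall together could beat the shuffles, so these counts do not separate position from level. All rose in 6 runs, which shuffled calls reached (mean 2.98, at most 9). Among those 6, the run from 645237 to 655160 (6 tested frames, reverse strand) had a median change of 2.67 and lies inside the block that rose at 4 h.

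As regions, 4 of 219 bins were called lower at 10 d and 0 higher. From 740831 to 760474, 15 of 18 measured frames were lower and 2 higher, with a median of -1.14. From 2179193 to 2200821, 6 of 9 were lower (median -1.88), from 2900070 to 2919848, 4 of 6 (median -1.38), and from 2439991 to 2460314, 4 of 7 (median -1.28). Over all 20 tested frames of the last region, most not measured at 10 d, 8 were higher and 7 lower (median 0.45). Over all 29 from 740831 to 760474, 7 were higher and 18 lower (median -0.86). With an estimated correlation camera called none (smallest adjusted p = 0.986, with 5 bins at an unadjusted p under 0.05), and fry, which also counts the shift shared by the frames measured in both groups (median 0.55), called 173. In simulated data, camera with an estimated correlation gave a planted 4-fold bin of 9 frames an adjusted p of 0.067 with each frame's own spread. With moderated spreads it gave 0.022, so this test can miss such a bin. Simulated frames varied independently, so this does not vouch for the preset correlation. Frame 4658569_4658787 was not well above background at 10 d and lay at least 2.92-fold below the inoculum (limma adjusted p = 0.000323). Frame 160386_161594 was still 13.3-fold above the inoculum (log2 change 3.73 ± 0.40 SE, n = 3 per group, limma adjusted p = 6.37e-05). With a common floor for all arrays its change was 0.50 and was no longer called. That floor was the highest array limit (0.30), well above the inoculum mean of this frame (-3.24) and near its 10 d mean (0.49). It therefore cut most of this rise by construction.

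Among the 1921 frames measured in both groups, limma called 855 higher and 287 lower at 10 d, with rises of up to 126-fold and falls of up to 37.8-fold. Fitting only the 6 arrays compared gave 734 and 222. The share of higher calls among these frames was 74.9%, against 82.9% with median scaling, 62.4% with the percentile over spots detected on all 9 arrays, 61.7% with quantile scaling and 51.5% with normexp. A frame dim at 10 d could not enter this set. Of the 704 frames brightest in the inoculum, 601 were measured at 10 d, and among these 128 were called higher and 216 lower. Over all 6353 frames, 2467 were higher and 1167 lower, of which 1610 of the higher ones were not measured on all arrays at 10 d, so these carry no measured rise. Of the 1167 lower ones, 287 were measured in both groups and 155 were lower as bounds, 40 of them by at least 2-fold and 1 by at least 24.7-fold. Another 438 were measured on only some arrays at 10 d, and for the remaining 287 the bound shows no fall. The split of all calls was 1344 to 1657 with quantile scaling, 482 to 609 with a common floor, 4280 to 1175 with normexp and 1194 to 1542 with normexp and quantile scaling. In simulated data 39.1% of the calls of this fit at 10 d were false with each frame's own spread and 22.5% with moderated spreads, above the 5% that the threshold aims at. Far fewer frames were changed in the simulation than the 3634 called here. A false share depends on that number, so these shares do not estimate how many of the real calls are false. The 10 d arrays lay on a slide of their own, so slide and time cannot be told apart.

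Between the soil times, part of the block from 600128 to 679949 and the block from 160386 to 179624 were lower at 10 d. From 640704 to 679949, 12 of 17 measured frames were lower at 10 d than at 4 h and 2 higher, with a median change of -2.52. In that stretch 14 of the 17 were higher than in the inoculum at 10 d, with a median of 1.52, and 12 were higher at both times. From 160386 to 179624, all 9 measured frames were lower than at 4 h (median -1.82), and 3 of the 9 remained above the inoculum. Frame 655149_655253 was not well above background at 10 d and lay at least 7.59-fold below its 4 h level (limma adjusted p = 1.17e-05). The regions from 740831 to 760474, from 2179193 to 2200821 and from 2439991 to 2460314 were also lower than at 4 h, with medians of -0.64, -0.75 and -0.86 among measured frames. Over all 20 tested frames of the last one, 11 were higher and 4 lower than at 4 h (median 1.23). With an estimated correlation none of these regions was called between the soil times (smallest adjusted p = 0.919). In simulated data this camera test gave a planted 4-fold bin of 9 frames an adjusted p of 0.016 with each frame's own spread. With moderated spreads it gave 0.108, so it can miss such a bin.

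**Figure D3:**
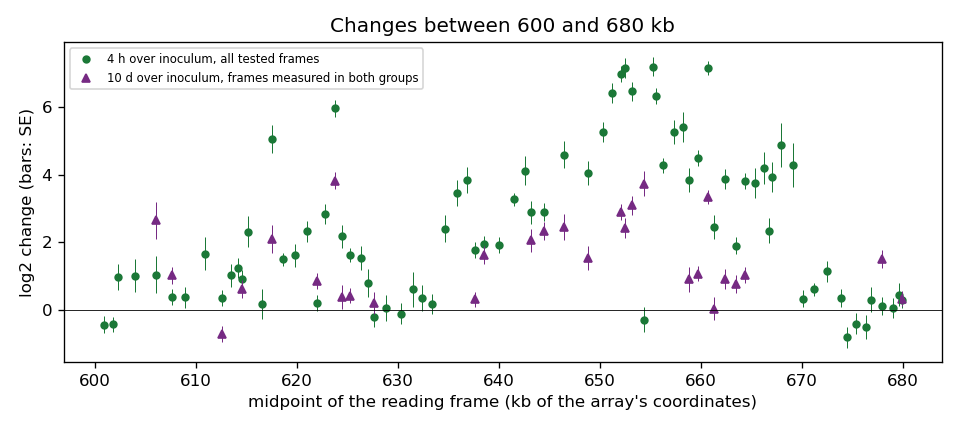
Log2 change against the inoculum (vertical axis, bars are SE of the fit) by midpoint of the reading frame (kb), circles for the 79 tested frames at 4 h and triangles for the 29 frames measured in both the inoculum and at 10 d. Most triangles lie below the circles of the same frames, and 18 of the 29 frames were called lower at 10 d than at 4 h.

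In runs, all tested frames were lower at 10 d than at 4 h in 8 of 46, where shuffled calls gave a mean of 0.10 and at most 2, and all were higher in 3 (mean 2.24). These shuffles did not keep signal level either, and the changes went with the level in the inoculum (r = -0.556). Changes of neighbours within runs correlated with r = 0.680, and with 0.692 after that trend was removed. The lower runs included those from 160386 to 163284 (median -3.65), from 659312 to 668655 (median -2.88) and from 2442947 to 2445044 (median -2.86). Camera called 6 of 220 bins lower and 0 higher, with an estimated correlation none was called and 6 had an unadjusted p under 0.05, and fry, again against no change, called 170. Of 1922 frames measured in both groups, 782 were higher at 10 d and 299 lower, or 646 and 241 in the fit of the 6 arrays. The share of higher calls among them was 72.3%, and 48.8% with normexp. Over all frames the counts were 2487 and 990. Of the higher ones, 1704 were not measured on all arrays at 10 d, and of the lower ones 299 were measured in both groups and 114 lower as bounds, while 353 were measured on only some arrays and the bound of 224 shows no fall. With each frame's own spread, 39.2% of the calls in simulated data were false, and 24.5% with moderated spreads. The fit of the 6 arrays gave 13.8% and 2.66% in turn. Far fewer frames were changed in the simulation than called here, so these shares do not carry over to the real calls.

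Of the 1918 frames measured on all 9 arrays, 141 were higher and 56 lower at 4 h, and 852 and 287 at 10 d. Higher at both times were 101, where independent lists would share 62.6, and lower at both times were 47, where they would share 8.38. Simulated unchanged soil groups against the same inoculum arrays shared a mean of 0 and 0.050. Unchanged groups give almost no calls, so this overlap was bound to be near 0. It does not show what lists of the observed lengths would share through the inoculum arrays. Of the 141 frames higher at 4 h, 63 were lower at 10 d than at 4 h, 35 were higher still and 43 did not pass the test. Without 10 d replicate 2 the counts at both times were 247 and 135, and without 1 other array as few as 62 and 16. Over all 6353 tested frames, most of them not measured at 10 d, 205 were higher and 168 lower at both times, 158 rose and were then lower, and 68 fell and were then higher. Changes at the 2 times correlated across frames with r = 0.42, and r = 0.26 in the simulation. Their covariance was 0.481 against a simulated 0.019, and frames are not independent replicates. The 3 inoculum arrays are too few to split into parts of at least 2, so part of the excess in overlap may come from the shared arrays. For the covariance, the simulated 0.019 already holds the spread among these arrays. The observed 0.481 argues against that spread as its main source. A deviation common to all 3 inoculum samples would not show in their spread and stays open.

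**Figure D4:**
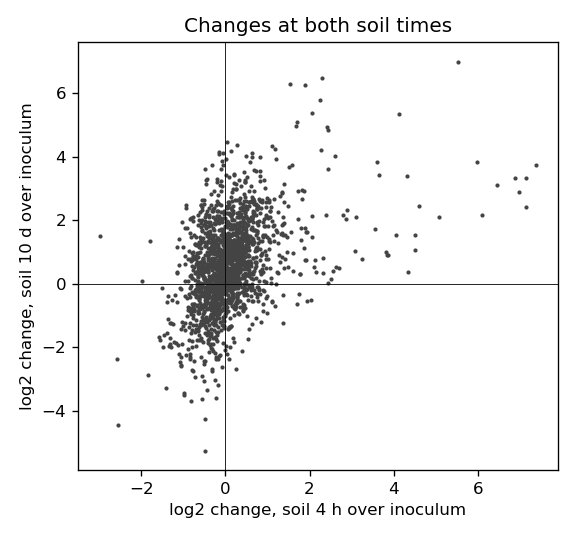
Log2 change at 10 d over the inoculum (vertical axis) against that at 4 h (horizontal axis), 1 point for each of 1921 frames measured in all 3 groups. The correlation over the 1918 frames measured on all 9 arrays by the same spot was 0.42.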

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

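Tests of the scaling percentile, of the array row and of the extraction kit were chosen after the results were seen, as were the values per region, those of frames chosen by their 4 h signal and those with the trend on level removed.

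Several results stood out because the change between the soil times passed a test of its own, for regions only at the preset correlation, since with an estimated one the smallest adjusted p was 0.919. The median change from 4 h to 10 d was -2.52 from 640704 to 679949, -1.82 from 160386 to 179624, -0.86 from 2439991 to 2460314, -0.75 from 2179193 to 2200821 and -0.64 from 740831 to 760474, and frame 160386_161594 changed by -3.65. As a bound, with 10 d values under an array's limit set at that limit, the fall of this frame was at least 10.8-fold. Of the frames measured on all 9 arrays, 7 were called in opposite directions at the 2 soil times and also between them. A signal also appeared in control spots that no comparison used. Probe ETG10_234183 had a mean log2 signal, without scaling, of 6.50 on the inoculum arrays, 6.56 at 4 h and 2.20 at 10 d. The 75th percentile of the signal lay between 261 and 315 on the inoculum arrays and between 12.4 and 32.9 at 10 d. The lower value of the probe at 10 d thus goes with a loss of signal over the whole array and is not particular to it.

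The joint rise of neighbouring frames at 4 h was weighed against 3 technical explanations. With the array row as a block, 70 frames in the named regions were called higher, all among the 77 called without it, which argues against the row as the whole cause. Binding of other RNA to single probes was not settled by probe pairs. Both probes rose at least 2-fold in 69.1% of 68 frames where 1 did (95% interval 56.7 to 79.8), short of the 80% set as the bound. Changes of neighbours at 4 h correlated with r = 0.680 within runs and 0.092 on opposite strands (difference 0.588, 95% interval 0.503 to 0.668). Successive pairs share a frame, so this interval is too narrow, and pairs on opposite strands had no limit on distance. All frames rose in 9 runs, against at most 1 with shuffled calls. These values, for which no bound was set, argue against single probes as the whole cause. Other RNA binding along whole runs stays open. An effect of the soil extraction kit that lasts alike over both soil times was tested on frames whose 4 h level lay above the 10 d limits, with those not measured at 10 d at their bound. In the 2 regions with a median rise over 2-fold, from 600128 to 679949 and from 160386 to 179624, such frames changed from 4 h to 10 d by a median of -2.10 (n = 54, 95% interval -2.46 to -1.52). Less the change of other frames of like 4 h level this was -1.68 (-2.17 to -1.17). The first region alone gave -1.73 (n = 42, -2.23 to -1.29). The second alone gave -1.19 (n = 12, -2.07 to -0.75), with an interval that reaches past the bound of -1. Frames were resampled as if independent although neighbours change together, so these intervals are too narrow, and the step to 10 d also crosses slides. The values argue against such a lasting effect as the whole cause in the first region and leave it open in the second. In the other 3 named regions the value was -0.72 (n = 19, -0.82 to -0.0046), where the rise was too small for the bound of -1 to decide. A kit effect that differs between the soil times stays open, and a biological response to soil remains an open hypothesis.

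The excess of higher over lower frames among those measured at 10 d may be a product of which frames could be measured. The tenth of frames brightest in the inoculum, 704 frames, had a median change of -0.44 (95% interval -0.60 to -0.32) with unmeasured frames at their bound, the outcome written down beforehand for such a selection. Choosing by inoculum signal itself favours falls, and the tenth brightest at 4 h had a median of -0.08 (-0.19 to 0.04), which shows no excess of rises either. Since changes at 10 d went with the level in the inoculum (r = -0.651), neither choice can separate selection from a change that depends on level. Scaling was not settled, with 62.4% higher under the percentile over detected spots, between the bounds of 60% and 70%. Unspecific binding was not settled either. The changes of the 2 probes of a frame correlated with r = 0.755 across 298 frames (95% interval 0.685 to 0.811), above the bound of 0.3 written down beforehand. That bound was wrong for this pattern, since a shift common to all frames leaves r as it is and changes also went with the level in the inoculum (r = -0.651).

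Neighbouring frames changed together at 10 d. Changes of neighbours within a run correlated with r = 0.602 over 215 pairs and those of neighbours on opposite strands with r = 0.094 over 197 pairs. The difference was 0.509 (95% interval 0.340 to 0.686), or 0.404 (0.209 to 0.594) with the trend on the inoculum level removed. Pairs were resampled as if independent although successive pairs share a frame, so these intervals are too narrow. Pairs within runs lay at most 50 nt apart and those on opposite strands had no such limit, so distance is mixed with strand. The difference argues against binding without regard to strand, run and distance as the whole cause. Other RNA that binds along a whole run would give the same difference, so the test does not decide on it. Array position is not settled either, since the place of spots on the array was not set against their coordinates. Slide and time cannot be told apart, and transcription of neighbouring frames as a unit stays a hypothesis.

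For each comparison the 6 arrays form 10 splits, too few for a share under 0.05. The real split of 4 h against the inoculum called 556 frames and the highest other split 0, and in each comparison 1 split, the real one, gave as many. The values were 3634 and 0 for 10 d against the inoculum and 3477 and 0 for 10 d against 4 h.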

How the results depend on the processing

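Settings chosen after seeing the data were the percentile over detected spots, the common floor, frames measured in both groups, bins of 50 kb, estimated correlations and fry. Counts below differ from the main ones by over 1.5 times, and the cause was not tested except where fewer frames or arrays, or a stricter threshold, entered by construction. Main counts were 314 higher and 242 lower at 4 h, 2467 and 1167 at 10 d, and 2487 and 990 between soil times. Among frames measured on all 9 arrays, 101 were higher and 47 lower at both times, 63 rose and were then lower, and 8 fell and were then higher; such counts below refer to these frames. That limit was set late, after the settings had been run over all tested frames as designed, where the main counts were 205, 168, 158 and 68. Quantile normalization gave 1344 higher at 10 d, 1229 higher between soil times, 88 lower at both times, 18 that fell and were then higher, and r = 0.52 between the changes at both times. Normexp with the 75th percentile gave 653 higher and 1512 lower at 4 h, 4280 higher at 10 d, 4396 higher between soil times, 175 and 196 at both times, 209 up then lower, 130 down then higher, r = 0.31 and 9 bins at 4 h, and the region from 220009 to 240248 turned to -0.023. Normexp with quantile gave 384 lower at 4 h, 1194 higher at 10 d, 1101 higher between soil times, 141 lower at both times, 31 down then higher, r = 0.51 and 2 bins at 10 d. The authors' values gave 1409 higher at 10 d, 1269 and 1516 between soil times and r = 0.47. A fit and adjustment over only the frames measured on all 9 arrays gave 194 and 104 at 4 h, 900 and 313 at 10 d, 828 and 321 between soil times, 29 down then higher and 7 bins at 4 h, and the region from 220009 to 240248 turned to -0.080. Single probes gave 156 higher at both times and 25 down then higher, and trend and robust settings gave 18 down then higher. The 6 arrays compared gave 1048 and 1741 at 4 h, 269 and 129 at both times and 114 down then higher. A 2-fold minimum gave 25 lower at both times and 3 down then higher, and an adjusted p under 0.01 gave 194 and 82 at 4 h, 63 and 18 at both times and 3 down then higher. Array weights gave 1107 and 1852 at 4 h, 336 and 169 at both times, 122 up then lower, 187 down then higher and r = 0.39. The percentile over detected spots gave 876 lower at 4 h, 128 lower at both times and 73 down then higher. A common floor gave 482 and 609 at 10 d, 375 and 552 between soil times, 77 lower at both times, 13 down then higher, r = 0.38 and 7 bins at 4 h. A fit over only the frames measured in both groups gave 903 and 313 at 10 d, 832 and 321 between soil times and 9 bins at 4 h. Bins of 50 kb gave 4 called at 4 h and 0 at 10 d, estimated correlations gave 0 in each comparison, and fry, which tests each bin against no change, gave 173 at 10 d and 170 between soil times.

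Leaving out 1 array at a time gave 192 to 786 higher and 77 to 1268 lower at 4 h, 62 to 247 and 16 to 135 at both times, 45 to 115 up then lower, 3 to 133 down then higher and r from 0.39 to 0.44. The highest of these counts came without 10 d replicate 2. With the replicate block, 265 and 172 were called at 4 h, 2421 and 1126 at 10 d, and 2451 and 938 between soil times, with 26 lower at both times and 5 down then higher. The rises from 160386 to 179624 lost their call with an estimated correlation and kept call and direction in the other settings run for them. Those from 600128 to 679949 lost the call in each of their bins with an estimated correlation, and in at least 1 bin among frames measured on all 9 arrays and with a common floor. Against no change, tested with fry, the largest adjusted p of these bins was 0.105. A block for the slide could not be fitted. What signal over background limits is the 10 d group, where 1923 of 7033 frames were measured.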

Other observations

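The 4 runs that fell below the inoculum at 10 d lay outside the 5 regions named as higher at 4 h. The run from 4045256 to 4046550 was lower at 10 d than at 4 h by a median log2 change of -1.58 and its frames had a median of -1.20 against the inoculum. The run from 55415 to 62910 was higher at 10 d than at 4 h (median 1.81) and than in the inoculum (median 1.67), with 4 tested frames, a kind of run that shuffled calls also gave.

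Spots of the 20 frames printed 11 or 12 times differed within an array by a median spread from 0.070 to 0.138 (log2) on the inoculum and 4 h arrays and from 0.130 to 0.210 on the 10 d arrays. The estimated array weights were between 1.43 and 3.06 for inoculum and 4 h arrays, and 0.585, 0.058 and 0.335 for 10 d replicates 1, 2 and 3, although replicate 2 had the highest share of spots above background of the 3. The median absolute difference between 10 d replicates 1 and 3 was 0.305, and those of replicate 2 with them were 0.852 and 0.884. On replicates 1 and 3, 6258 and 6497 of 12863 spots sat at the array's lowest value, and 1 on replicate 2. Frames held there on both replicates differ little, so the weights and differences do not rank array quality. Among frames measured on all 9 arrays, replicate 2 still correlated less with replicates 1 and 3 (r = 0.872 and 0.844) than these did with each other (0.923).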
